A study of Methylorubrum extorquens AM1 with 12 samples.

How the data were processed

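RNA-seq libraries of Methylorubrum extorquens AM1 from 6 times with 2 replicates each were compared. The times carry the labels T0, T120, T270, T540, T1080 and T1350, in minutes. The authors' processing notes name CASAVA, BWA 0.7.4-r385, SAMtools and HTSeq without saying what each did. The genome build, the annotation version, filters and the strand of counting are not given in the sources used here. The values used are the deposited score for each gene and sample, RPKM that the authors rounded to whole numbers. This unit was checked on the values: they are whole numbers in all 12 columns, and value times gene length over the matched genes sums to between 96.2 and 102% of the total that RPKM implies in each column. Since the values are not raw counts, models of counts were not used, the number of reads per sample is unknown and no counting interval can be given.

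The table holds 6742 features, of which 5299 belong to the chromosome, 1317 to the megaplasmid and 126 to plasmids. A RefSeq gene table of the AM1 genome matched 5952 of them (88.3%) by locus tag and gave 934 a symbol. It was used for symbols, gene lengths and neighbours, and products are those of the authors' table. Genes with at least 10 RPKM in at least 2 of the 12 samples were tested, 6277 in all, on log2(RPKM + 1).

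Each time was a group in 1 linear model over the 12 samples, fitted with limma 3.58.1 in R 4.3.3 and empirical Bayes moderation with a mean-variance trend. Each later time was compared with T0 and each time with the time before it, and an F test covered all 6 times. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 within each comparison as the threshold. A total of 30 gene lists with at least 4 measured members each were made from symbol and product patterns. They cover the ethylmalonyl-CoA pathway, propionyl-CoA to succinyl-CoA, mau genes, acetaldehyde and acetate to acetyl-CoA, polyhydroxybutyrate, the tricarboxylic acid cycle, C4 uptake with anaplerosis and pyruvate, the serine cycle, methanol oxidation with PQQ, C1 carriers, formate dehydrogenases and cobalamin. Others cover ribosomal proteins, translation factors with RNA polymerase, ATP synthase, NADH dehydrogenase, terminal oxidases, flagella, heat shock, oxidative stress, general stress with trehalose, nitrogen, iron, photosynthesis with carotenoids, hopanoids, amino acids, cell division, insertion sequences with phage, nucleotides and fatty acids. The lists were tested at each later time against T0 with camera at a preset correlation of 0.01, adjusted over the 150 tests. Camera with an estimated correlation and fry were run beside it, and the fry values are not reported here. Camera sets the changes of a list against those of all other genes, so a list can be called higher without having risen from T0. At either correlation, a list that camera does not call can still have moved from T0, and the member counts bear on that. Member counts are over all genes tested, and also adjusted over the list alone. The comparisons, lists, patterns, tests, first set of alternatives and naming rule were chosen before the data were examined.

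The rule covers the measured members of the ethylmalonyl-CoA, propionyl-CoA and mau lists with acs and phaR. It also takes, for each comparison with T0, up to 8 genes with the largest rise and 8 with the largest fall, and 3 of each between neighbouring times. These had adjusted p under 0.05, a mean of at least 50 RPKM in the higher group, both replicates beyond both of the other group, and a named product. From each list up to 4 members with the smallest adjusted p, rises and falls in turn, could be named. The symbols qscR, ccrR and acsA of the rule were not found.

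The replicate numbers proved to pair the samples: the difference between replicate 1 and replicate 2 correlated across genes between all 15 pairs of times, with r from 0.526 to 0.878, where genes are not independent replicates. This was decided before calls were compared. In a fit with the replicate number as a term 3789 of 6277 genes had a replicate effect, and the pooled residual SD was 0.31 log2 against 0.62 without the term. Where that term or median-ratio rescaling moves a printed count of a comparison or list by over 1.5 times, the moved value stands beside it.

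The alternatives were a pseudocount of 0.1 or 10, no filter or a filter of 50 RPKM, median-ratio rescaling, quantile normalization, no variance trend, only the 2 groups compared, the replicate term, a change of at least 2-fold, and leaving out each sample in turn, where the lone sample left is assumed to vary like the other groups. Chosen after seeing the data were the replicate term with median-ratio rescaling, fits without the 15 rRNA and 63 tRNA features with each library divided by the share of reads left, a common sum of RPKM per library, and the replicate term with an estimated list correlation. The first forms of 2 tests of the closing section were dropped after their results were seen. Taking out rRNA and tRNA moves all genes of a library by 1 small factor and could not have ended the replicate effects, and the slopes set beside that of T540 had been centred on each other. Their replacements were set after those results.

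The fit was tested on simulated data with the spreads of the real genes, 6277 genes of which 200 changed between T0 and T540. With independent noise it recovered 8% of 2-fold and 55% of 4-fold changes, with 4 false calls among 67. With noise shared by replicate number it recovered 3% and 52%, with 0 false among 55, and with the replicate term 53% and 91%, with 9 false among 153. In these simulations the fit without the replicate term left most 2-fold changes uncalled. In the real comparisons of T120, T270 and T540 with T0, 42.7 to 52.1% of genes were called. That many changes make the adjusted threshold easier to pass, so the simulated rates need not hold there. With 2 samples in a group, tests of outlying samples and of other splits of the samples were not run.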

Results

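Methylorubrum extorquens AM1 is a pink-pigmented bacterium that grows on methanol and methylamine as well as on ethylamine and succinate. Ethylamine is oxidised by way of acetaldehyde and acetate to acetyl-CoA, which this organism assimilates through the ethylmalonyl-CoA pathway. RNA was sequenced from succinate-limited chemostat cultures (T0) and from the same set-up after the medium flow was shut off and ethylamine supplied. The labels T120, T270, T540, T1080 and T1350 give the time since then in minutes. The series title asks about ethylmalonyl-CoA mutase as a control point of that pathway. Each of the 6 times had 2 samples, replicate 1 and replicate 2, which made 12 samples. The sample titles mark replicate 1 and replicate 2 as BR1 and BR2. The labels do not say whether these are cultures, library batches or both, so every p-value measures only the spread between these samples.

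Values are RPKM that the authors rounded to whole numbers, so the number of reads behind each sample is unknown. The sum of RPKM ran from 1343463 to 2106339 per sample and the median gene from 23 to 56 RPKM. Replicate 1 samples had 10448 to 59839 RPKM over the 5S rRNA genes, and replicate 2 samples 39.2 to 169. Weakly expressed genes were also higher in replicate 1, where 4.88 to 14.1% of genes lay under 10 RPKM, against 15.8 to 29.9% in replicate 2. Principal component 1 carried 72.6% of the variance and set the samples of T120, T270 and T540 apart from those of T0, T1080 and T1350. At T540 replicate 1 lay at 28.2 on this axis and replicate 2 at 78.7. Over the 6 times 3158 of 6277 genes (50.3%) changed (limma F test), and 5078 with a term for the replicate number.

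**Figure D1:**
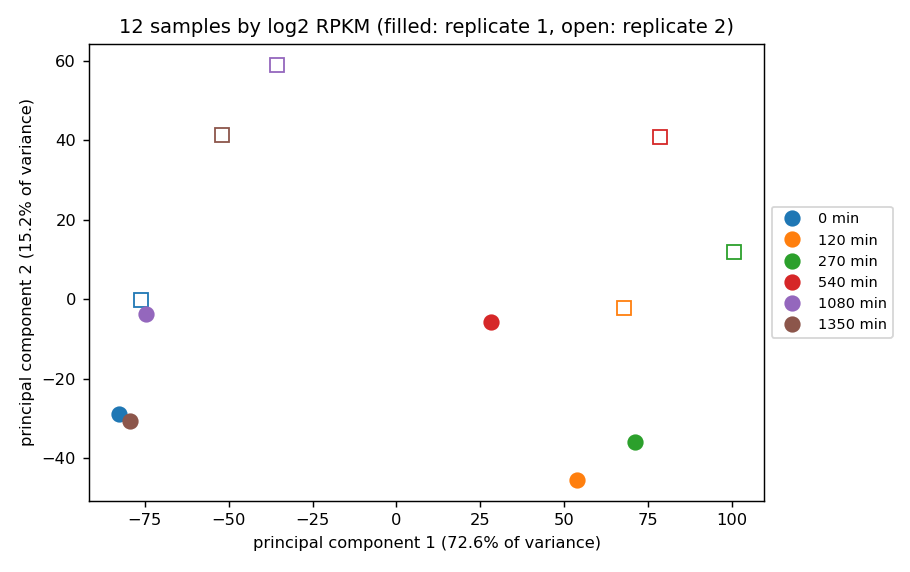
Each point is 1 of the 12 samples, placed by principal components 1 (72.6% of the variance) and 2 (15.2%) of log2 RPKM, with colour for the time in min and filled marks for replicate 1. The samples of T0, T1080 and T1350 have negative values on component 1 and those of T120, T270 and T540 positive values.

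Ethylmalonyl-CoA mutase (META1_0180), the cobalamin-dependent enzyme that turns ethylmalonyl-CoA into methylsuccinyl-CoA, stood at 249 ± 26.2 RPKM at T0 (mean ± SD, n = 2, as throughout). Its transcript rose to 525 ± 78.5 RPKM at T120, 471 ± 116 at T270 and 1338 ± 470.2 at T540, with log2 changes of 1.07, 0.90 and 2.38 (limma adjusted p = 0.025, 0.043 and 3.6e-04). At T1080 it was 754 ± 204 RPKM (limma adjusted p = 0.057, and 0.012 with a replicate term) and at T1350 607 ± 99.7 (adjusted p = 0.24). The gene for crotonyl-CoA carboxylase/reductase (ccrA), which makes ethylmalonyl-CoA, went another way. It fell from 503 ± 77.1 RPKM at T0 to 233 ± 34.6 at T270 (limma adjusted p = 0.01; 0.48 after median-ratio rescaling). The ccrA transcript then stood at 727 ± 105 RPKM at T540, 1026 ± 48.1 at T1080 and 1295 ± 45.3 at T1350. Against T0 these late values passed the threshold only with a replicate term (limma adjusted p = 0.026 at T1080 and 0.044 at T1350, against 0.18 and 0.11 without). The log2 ratio of mutase to carboxylase RPKM was -0.75 and -1.28 in the samples of T0, 0.41 to 1.11 in the 6 samples of T120 to T540, and -1.31 to -0.14 in the 4 later samples.

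**Figure D2:**
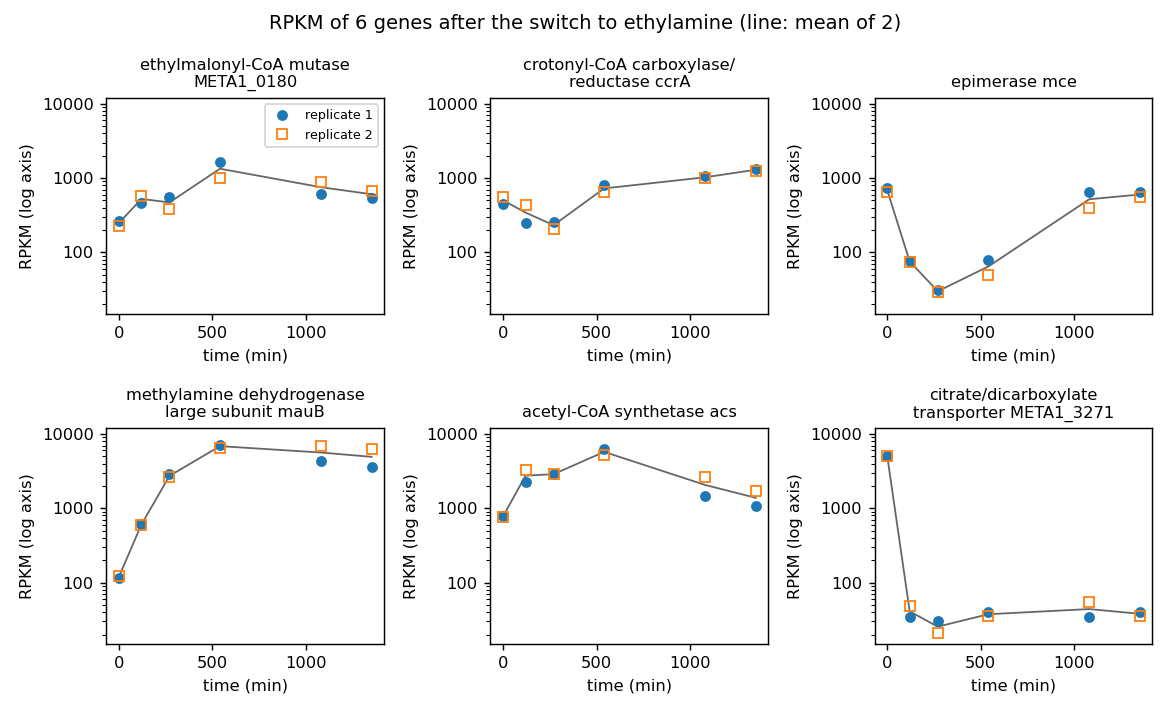
RPKM on a log axis against time in min for 6 genes, with a mark for each replicate and a line through the mean of 2. The mutase gene META1_0180 has its highest mean at T540 (1338 RPKM), ccrA its lowest at T270 (233) and highest at T1350 (1295), and META1_3271 runs from 5056 RPKM at T0 to between 25.5 and 44 later.

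Around these enzymes the pathway's genes moved in both directions at T120, when 6 of 17 measured members rose and 2 fell (6 and 3 adjusted over the list alone; 6 and 5 with a replicate term). Malyl-CoA lyase META1_1733 rose from 288 ± 41 to 919 ± 99 RPKM, acetoacetyl-CoA reductase phbB from 3006 ± 313 to 8859 ± 1185, beta-ketothiolase META1_3700 from 3246 ± 173 to 5830 ± 414, and the thiolase META1_3455 from 183 ± 2.12 to 318 ± 72.1. So did the methylmalonyl-CoA mutase subunit gene scpA, from 209 ± 14.1 to 470 ± 26.9. The search pattern of this list also matched methylmalonyl-CoA products. The mutase subunit genes scpA and META1_2390, of the route from propionyl-CoA, therefore count among the 17 too, and META1_2390 was among the falls at T270. META1_3455, also annotated for fatty acid oxidation, entered through the name beta-ketothiolase. The epimerase gene mce fell from 687 ± 53.7 to 75.5 ± 0.707 RPKM and mesaconyl-CoA hydratase META1_4153 from 397 ± 5.66 to 64.5 ± 14.8 (limma adjusted p = 3.4e-05 and 7.1e-05). The camera test gave adjusted p = 0.71 with the direction up, while the list's median was -0.23 and its mean -0.15; the median was 0.21 after median-ratio rescaling. At T270 4 members rose and 6 fell (4 and 6 adjusted over the list alone; 4 and 3 after median-ratio rescaling), and at T540 3 rose and 4 fell (2 and 2; 5 and 6 with a replicate term; 5 and 2 after median-ratio rescaling). By T540 scpA had risen to 1265 ± 233 RPKM and malyl-CoA lyase META1_4295 from 384.5 ± 13.4 to 735 ± 269, with mce at 64.5 ± 21.9 and META1_4153 at 43.5 ± 12, both still below T0. Of the genes that fell at T270, crotonase croR was at 180 ± 75 RPKM then and at 1049 ± 37.5 at T1080. The T1080 value was tested against T0, not against T270 (limma adjusted p = 0.11, and 0.011 with a replicate term).

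Propionyl-CoA, which the pathway also releases, is carboxylated and rearranged to succinyl-CoA. Of 7 genes for that route, 1 rose and 3 fell at T120 (1 and 4 adjusted over the list alone; 1 and 5 with a replicate term), with camera adjusted p = 0.17. The member that rose was scpA. The propionyl-CoA carboxylase genes META1_0172 and META1_3203 fell from 682 ± 66.5 and 353 ± 1.41 RPKM to 224 ± 21.2 and 113 ± 8.49, and further to 131 ± 11.3 and 66.5 ± 10.6 at T270. The beta subunit gene of methylmalonyl-CoA mutase, META1_2390, fell from 147 ± 29 to 52 ± 15.6 RPKM at T270. Its values at T120 and T540 passed only with a replicate term (limma adjusted p = 0.0016 and 0.0018, against 0.073 and 0.074). At T1080 the carboxylase genes were at 799.5 ± 194 and 359.5 ± 96.9 RPKM.

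The mau genes, for methylamine dehydrogenase and the proteins that mature it, rose more than any other list: 7 of 8 at T120 (7 adjusted over the list alone, 8 with a replicate term) and 8 of 8 at each later time (8 adjusted over the list alone). The large subunit gene mauB went from 120 ± 5.66 RPKM at T0 to 603 ± 11.3, 2731 ± 186, 6865 ± 414, 5634 ± 1869 and 4929.5 ± 1817. The small subunit gene mauA went from 171 ± 14.1 to 6392 ± 1580.4 at T540 and 6537 ± 485 at T1350, and mauF from 129 ± 14.1 to 7344 ± 1470.1 and 4537 ± 1401. The maturation gene mauG was the member short of the threshold at T120 (limma adjusted p = 0.23, and 0.023 with a replicate term) and rose from 26.5 ± 4.95 to 341 ± 136 RPKM at T540. The list's median log2 change was 1.91, 3.85, 5.29, 5.40 and 5.14 (camera adjusted p = 1.3e-04, 1.2e-07, 2.4e-10, 3.5e-42 and 2.2e-60). With an estimated correlation the adjusted p was 0.69, 0.38 and 0.28 at T120 to T540, and the call held at T1080 (adjusted p = 0.023) and at T1350 (adjusted p = 0.016), the 2 list calls of 82 that did. With the replicate term as well neither held (adjusted p = 0.24 and 0.24). The list's search pattern missed napG and napH, annotated MauM and MauN, and amicyanin (META1_2774), the copper protein that takes electrons from the dehydrogenase. Amicyanin is named by the rule at T1350. It had risen from 209 ± 2.12 RPKM at T0 to 750 ± 42.4 by T120 (limma adjusted p = 3.5e-04). At T1080 it stood at 8856 ± 810 and at T1350 at 8228 ± 1220.5.

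Of the genes that rose furthest against T0 by T120, the polyhydroxybutyrate depolymerase META1_4597 rose from 43 ± 4.24 to 2523 ± 412 RPKM and the patatin-like phospholipase META1_4294 from 18.5 ± 3.54 to 826 ± 71.4. The response regulator META1_4500 rose from 36 ± 2.83 to 1589 ± 345 and the hemolysin III family gene trhA from 116 ± 19.8 to 4599.5 ± 637. The Dps family gene META1_5227 rose from 135 ± 44.5 to 4419.5 ± 853 RPKM. The general stress proteins META1_0650 and META1_5012 rose from 73 ± 7.07 and 225 ± 82.7 to 2384 ± 218 and 6490 ± 1399. The topoisomerase gene META1_1949 rose from 31.5 ± 3.54 to 1184 ± 47.4 RPKM. The furthest fall was that of META1_3271, a transporter annotated for citrate and dicarboxylic acids, from 5056 ± 20.5 to 41 ± 9.9 RPKM (log2 change -6.93, limma adjusted p = 4.8e-06). The CoxB-related gene META1_4266 fell from 5799 ± 1055 to 85 ± 11.3 RPKM and the outer-membrane protein META1_4887 from 9436 ± 494 to 158 ± 59.4. In all 1088 genes rose and 1595 fell of 6277 (limma), around a median log2 change of -0.38 over all genes. With median-ratio rescaling, which sets that median near 0, 1603 were higher and 1567 lower, and with a replicate term 1521 and 2702. Without replicate 2 of T120 980 were lower, and without replicate 1 or 2 of T0 1018 or 1039.

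At T120 all 54 ribosomal protein genes fell (54 adjusted over the list alone; median log2 change -4.39), among them rpsF from 4859 ± 133 to 80 ± 12.7 RPKM, rpsL from 3606 ± 309 to 64 ± 1.41 and rplK from 3793 ± 621 to 82 ± 18.4. Of 20 translation factor and RNA polymerase genes 17 fell (18 adjusted over the list alone; 1 rose with a replicate term and 1 after median-ratio rescaling), with elongation factor fusA from 2795 ± 198 to 65.5 ± 10.6 RPKM and tsf from 1297 ± 156 to 61 ± 12.7. ATP synthase genes fell in 11 of 13 cases (12 adjusted over the list alone), as atpA did from 2284 ± 166 to 90.5 ± 16.3 RPKM. Genes of NADH dehydrogenase, the entry to the respiratory chain, fell in 15 of 18 (15), as nuoL did from 662 ± 33.9 to 66 ± 8.49. Camera gave adjusted p = 1.8e-25, 1.6e-06, 9.4e-06 and 9.4e-06 for these 4 lists in turn, and adjusted p = 0.69 with an estimated correlation for each. Of 23 genes for terminal oxidases and the cytochrome bc complex, 2 rose and 10 fell (2 and 10 adjusted over the list alone; 4 and 11 after median-ratio rescaling; camera adjusted p = 0.04997, or 0.085 with a replicate term, 0.19 after median-ratio rescaling, and adjusted p = 0.72 with an estimated correlation). Those that rose were the cytochrome bd genes META1_1952 (from 51.5 ± 0.707 to 373 ± 19.1 RPKM) and cydB (from 54.5 ± 0.707 to 330 ± 32.5), whose product is known for its high affinity for oxygen. Cytochrome c oxidase ctaD fell from 1207 ± 296 to 228 ± 16.3.

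Flagellar and chemotaxis genes fell in 76 of 94 cases at T120 and 2 rose (78 and 4 adjusted over the list alone; 85 and 4 with a replicate term; 79 and 5 after median-ratio rescaling), with the hook gene META1_0508 going from 317 ± 36.1 to 20.5 ± 0.707 RPKM. Amino acid synthesis had 38 of 63 genes lower and 4 higher (39 and 4 adjusted over the list alone; 33 and 7 after median-ratio rescaling), such as methionine adenosyltransferase metK from 939 ± 40.3 to 174 ± 32.5 RPKM. Purine and pyrimidine synthesis had 16 of 19 lower (16), such as carA from 258 ± 14.1 to 28.5 ± 2.12. Cell division, replication and envelope genes fell in 22 of 31 cases and rose in 2 (22 and 2 adjusted over the list alone). The division gene ftsZ fell from 407 ± 0.707 to 28 ± 2.83 RPKM. Those that rose were 2 copies of the protease gene ftsH, META2_0910 (from 464 ± 6.36 to 1077 ± 185) and META1_5299 (from 629.5 ± 3.54 to 1138 ± 149). Genes for hopanoids, sterol-like membrane lipids, and isoprenoids fell in 13 of 14 cases (13 adjusted over the list alone), as squalene-hopene cyclase shc did from 428 ± 65.8 to 101 ± 4.95 RPKM. Iron and TonB uptake genes fell in 19 of 38 cases and rose in 1 (20 and 1 adjusted over the list alone; 15 and 3 after median-ratio rescaling; 29 and 2 with a replicate term), as the receptor META1_1785 did from 878 ± 116 to 25 ± 5.66. For these 6 lists in turn the camera adjusted p was 1.6e-10, 9.6e-05, 5.3e-05, 3.4e-04, 9.5e-05 and 0.0021, and adjusted p = 0.69 with an estimated correlation for each.

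In central carbon metabolism 8 of 13 tricarboxylic acid cycle genes fell at T120 (8 adjusted over the list alone; 2 after median-ratio rescaling), such as citrate synthase gltA from 1262 ± 133 to 515 ± 111 RPKM and the succinyl-CoA synthetase gene sucD (META1_1539) from 1216 ± 156 to 384.5 ± 177. The camera adjusted p of 0.014 became 0.069 with a replicate term, 0.1 after median-ratio rescaling, and the adjusted p = 0.69 with an estimated correlation. Of 21 genes that carry formaldehyde and formate on tetrahydromethanopterin or tetrahydrofolate 13 fell (14 adjusted over the list alone; 1 rose with a replicate term and 1 after median-ratio rescaling), such as fhcD from 346 ± 29.7 to 46 ± 2.83 RPKM and mch from 437 ± 19.8 to 90.5 ± 7.78 (camera adjusted p = 0.0033, and adjusted p = 0.69 with an estimated correlation). Between acetaldehyde and acetyl-CoA 5 of 10 genes rose and 0 fell (5 and 1 adjusted over the list alone; 5 and 2 with a replicate term; 5 and 1 after median-ratio rescaling). Acetyl-CoA synthetase acs, which activates acetate, rose from 780 ± 21.2 to 2750 ± 713 RPKM and on to 5752 ± 816 at T540. The aldehyde dehydrogenase gene adh (META1_3652), singled out after its values were seen, rose from 2315 ± 682 to 14081 ± 4681 and 37164 ± 7770.4. The polyhydroxybutyrate cycle had 4 of 10 genes higher and 1 lower (5 and 1 adjusted over the list alone; 5 and 2 with a replicate term), among them the granule protein gene META1_2529 from 2737 ± 120.2 to 14184 ± 1527 RPKM. The gene that fell was maiA, a maleylacetoacetate isomerase of tyrosine breakdown, and a fumarylacetoacetate hydrolase gene, META1_3706, was among those that rose. Dicarboxylate uptake, anaplerotic and pyruvate genes moved both ways, 4 up and 2 down of 19 (4 and 2 adjusted over the list alone; 4 and 4 after median-ratio rescaling; 5 and 4 with a replicate term). Pyruvate oxidase poxB rose from 35.5 ± 7.78 to 544 ± 98.3 and pyruvate kinase pyk fell from 281 ± 21.9 to 32.5 ± 0.707. The search pattern of that list did not take in META1_3271. Camera gave adjusted p = 0.098, 0.095 and 0.51 for the last 3 lists in turn.

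The serine cycle, by which methylotrophs fix formaldehyde carbon, had 2 of 12 genes higher and 3 lower at T120 (2 and 3 adjusted over the list alone; 3 and 1 after median-ratio rescaling; camera adjusted p = 0.95). Hydroxypyruvate reductase META1_1727 rose from 307 ± 38.9 to 842 ± 10.6 RPKM and enolase eno fell from 746 ± 25.5 to 302 ± 75. Methanol oxidation and pyrroloquinoline quinone genes had 2 up and 1 down of 14 (2 and 0 adjusted over the list alone; 2 and 0 after median-ratio rescaling; camera adjusted p = 0.18). Those that rose were a PQQ-dependent sugar dehydrogenase, META1_4884, and an aldehyde dehydrogenase, META2_0885, neither of which oxidises methanol by its annotation. Formate dehydrogenase genes had 2 up and 2 down of 13 (2 and 2 adjusted over the list alone; 4 and 2 after median-ratio rescaling; 6 and 4 with a replicate term; camera adjusted p = 0.38). Of 25 genes for cobalamin, the cofactor of both CoA mutases, 1 rose and 7 fell (1 and 6 adjusted over the list alone; 3 and 11 after median-ratio rescaling; 2 and 20 with a replicate term). The gene cobJ rose from 159 ± 5.66 to 1405 ± 947 RPKM and cobW fell from 513 ± 149 to 90 ± 46.7. Camera gave that list adjusted p = 0.074, 0.02 with a replicate term, 0.042 after median-ratio rescaling and adjusted p = 0.74 with an estimated correlation. Fatty acid genes had 8 up and 24 down of 53 (8 and 24 adjusted over the list alone; 12 and 33 with a replicate term). Acyl carrier protein META1_0378 fell from 10459 ± 2821 to 928 ± 123 RPKM and the acyl-CoA dehydrogenase META1_3716 rose from 33 ± 0 to 425 ± 48.8 (camera adjusted p = 0.065, 0.047 after median-ratio rescaling, and adjusted p = 0.74 with an estimated correlation).

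At T120 heat shock and protease genes had 13 up and 11 down of 35 (14 and 12 adjusted over the list alone; camera adjusted p = 0.16). The chaperonin genes groL and groES fell from 7809.5 ± 2413 and 7422 ± 905 RPKM to 161 ± 59.4 and 159 ± 24.7, while grpE rose from 134 ± 2.83 to 1824 ± 35.4. Oxidative stress genes had 7 up and 3 down of 22 (7 and 3 adjusted over the list alone; 9 and 6 with a replicate term; camera adjusted p = 0.12), with methionine sulfoxide reductase msrA from 92.5 ± 2.12 to 697 ± 82 RPKM. General stress response and trehalose genes had 7 up and 3 down of 21 (7 and 3 adjusted over the list alone; 7 and 5 with a replicate term; camera adjusted p = 0.17). The gene treZ, for trehalose release, rose from 134 ± 18.4 to 583 ± 9.19. The protein export genes secD and secF, which the pattern took in, fell from 395 ± 16.3 and 279 ± 29.7 to 43.5 ± 2.12 and 41 ± 8.49. Nitrogen assimilation genes had 7 up and 10 down of 35 (8 and 10 adjusted over the list alone; camera adjusted p = 0.92). The urease accessory gene ureE rose from 8 ± 4.24 to 86.5 ± 47.4 RPKM and on to 450 ± 19.8 at T270. Photosynthesis and carotenoid genes had 6 up and 2 down of 34 (5 and 2 adjusted over the list alone; camera adjusted p = 0.0071, and adjusted p = 0.69 with an estimated correlation). Those that fell were hpnC and hpnD, phytoene synthase homologues of hopanoid synthesis. Insertion sequence and phage genes had 43 up and 13 down of 249 (11 and 7 adjusted over the list alone; 135 and 9 after median-ratio rescaling; 126 and 41 with a replicate term), with a median log2 change of 0.60 (camera adjusted p = 5.2e-05, and adjusted p = 0.69 with an estimated correlation). A transposase of ISMex32, META2_0161, rose from 7.5 ± 2.12 to 179 ± 53.7 RPKM.

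**Figure D3:**
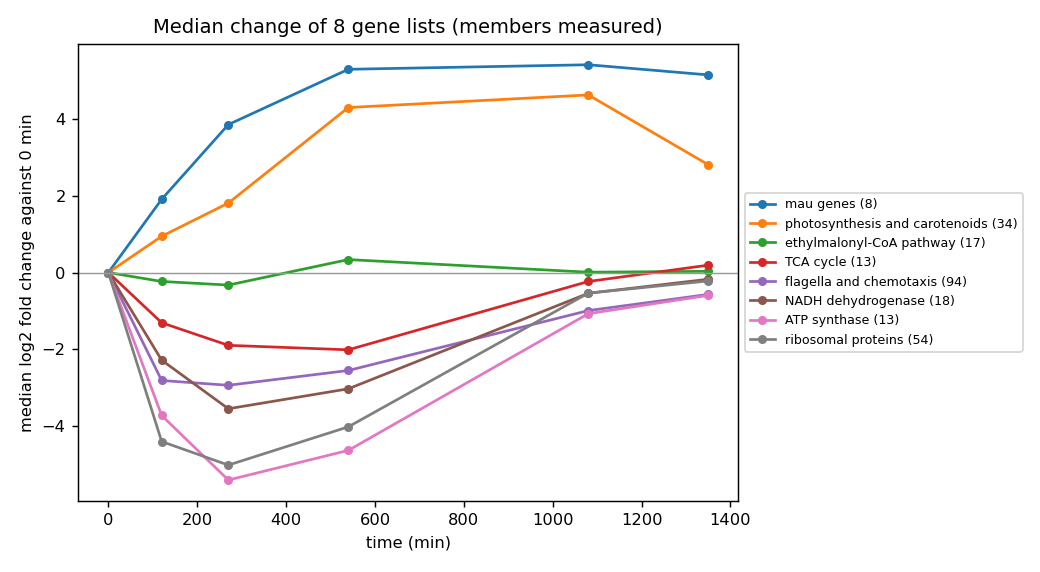
Lines give the median log2 change against T0 of 8 gene lists at each time in min, with the number of measured members in the key. The mau list has its highest median at T1080 (5.40) and the ribosomal protein list its lowest at T270 (-5.01). The ethylmalonyl-CoA list stays between -0.33 and 0.34, with a sign that depends on the scaling at every time, as does that of the TCA cycle list at T1080 and T1350.

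At T270 META1_4294 had risen to 1286 ± 88.4 RPKM, META1_4500 to 2429.5 ± 429, the depolymerase META1_4597 to 2638 ± 270.1, META1_0650 to 4189 ± 176, trhA to 6123 ± 518, META1_1949 to 1596 ± 184 and META1_5227 to 5821 ± 1526. META1_3271 had fallen to 25.5 ± 6.36 RPKM (log2 change -7.60), META1_4887 to 75.5 ± 31.8 and META1_4266 to 45.5 ± 14.8. The flagellin gene META1_0502 fell from 1545 ± 315 to 15 ± 9.9, rpsR from 3890 ± 314 to 35.5 ± 9.19 and rpsJ from 4239.5 ± 3.54 to 51 ± 2.83. In all 1061 genes rose and 2210 fell of 6277 (limma), around a median log2 change of -0.63. With median-ratio rescaling 1821 were higher and 1843 lower, and without replicate 2 of T270 1408 were lower.

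Among the lists at T270, 54 of 54 ribosomal protein genes fell (54 adjusted over the list alone; median log2 change -5.01), 12 of 13 ATP synthase genes (12; -5.40), 15 of 18 NADH dehydrogenase genes (16; -3.54) and 12 of 13 tricarboxylic acid cycle genes (12; -1.89; 6 after median-ratio rescaling). Camera gave adjusted p = 5.0e-22, 1.0e-05, 3.2e-06 and 0.0018 for these in turn, and adjusted p = 0.69 with an estimated correlation for each. The terminal oxidase list, with 2 genes higher and 13 lower of 23 (2 and 13 adjusted over the list alone), was called lower (camera adjusted p = 0.018, and adjusted p = 0.69 with an estimated correlation). Photosynthesis and carotenoid genes rose in 11 of 34 cases (6 adjusted over the list alone; 18 with a replicate term and 18 after median-ratio rescaling; camera adjusted p = 2.2e-04, and adjusted p = 0.69 with an estimated correlation). Heat shock and protease genes, 16 up and 14 down of 35 (16 and 14 adjusted over the list alone; 16 and 9 after median-ratio rescaling), were called only with a replicate term (camera adjusted p = 0.047, against 0.097 without and an adjusted p = 0.69 with an estimated correlation).

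Between T120 and T270 13 genes rose and 12 fell of 6277 (limma). The amidotransferase gene META1_1550 and the glutamate synthase-like gene META1_1551 rose from 64.5 ± 31.8 and 76 ± 25.5 RPKM to 667 ± 12.7 and 735 ± 23.3. Ornithine cyclodeaminase META1_3003 rose from 65 ± 28.3 to 612 ± 100.4. The methanol oxidation genes META1_4528 (MxaD) and META1_4527 (MxaE) fell from 352 ± 31.8 and 181 ± 26.9 RPKM to 50 ± 25.5 and 27 ± 14.1. Of the 25 calls none was kept after median-ratio rescaling, which gave 1 other gene, and the median over all genes was -0.24. With a replicate term 46 were higher and 395 lower, while leaving out 1 sample gave from 0 to 29 calls (limma; 674 genes at an unadjusted p under 0.05 with all samples).

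At T540 light-harvesting genes stood beside the mau genes among the highest rises. The genes pufA and pufB, for the light-harvesting complex of aerobic anoxygenic phototrophy, rose from 133 ± 68.6 and 139 ± 97.6 RPKM to 7943 ± 948 and 8197 ± 4339.5 (limma adjusted p = 0.0017 and 5.9e-04). META1_2927, for a bacteriochlorophyllide reductase subunit, rose from 19 ± 15.6 to 941 ± 367. META1_1550 (an amidotransferase), META1_1552 (an FMN-dependent dehydrogenase) and glnT (gamma-glutamylmethylamide synthetase) rose from 17 ± 2.83, 22 ± 5.66 and 32 ± 4.24 RPKM to 1084 ± 194, 1269 ± 119 and 1681 ± 309.7. META1_3271 was at 37.5 ± 3.54 RPKM, and the chaperonin genes groL and groES had fallen to 89.5 ± 12 and 96.5 ± 40.3. META1_1357, for the ATP synthase epsilon subunit, fell from 1791 ± 491 to 45.5 ± 10.6 RPKM and rplI from 1489 ± 19.1 to 38.5 ± 26.2. In all 1017 genes rose and 2048 fell of 6277 (limma), around a median log2 change of -0.61. With median-ratio rescaling 1714 were higher and 1773 lower, and with a replicate term 1340 and 3154. Without replicate 2 of T540 1915 genes were called, 1144 of them lower, and without replicate 1 of T0 1294 were lower.

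Photosynthesis and carotenoid genes rose in 25 of 34 cases at T540 (25 adjusted over the list alone; median log2 change 4.29), such as bacteriochlorophyll synthase chlG from 44 ± 15.6 to 638 ± 199 RPKM and phytoene dehydrogenase META1_3219 from 24.5 ± 10.6 to 356 ± 114. Camera gave adjusted p = 6.5e-10, and adjusted p = 0.69 with an estimated correlation. Ribosomal protein genes still fell in 54 of 54 cases (54 adjusted over the list alone; median log2 change -4.01), flagellar genes in 78 of 94 (80; -2.55) and carbon transfer genes on tetrahydromethanopterin or tetrahydrofolate in 19 of 21 (20; -2.24). Camera gave adjusted p = 2.1e-21, 4.7e-08 and 1.1e-04 and adjusted p = 0.69 with an estimated correlation for each. Cobalamin genes fell in 14 of 25 cases and rose in 1 (15 and 1 adjusted over the list alone; 13 and 2 after median-ratio rescaling; camera adjusted p = 0.035, and adjusted p = 0.74 with an estimated correlation), with cobW at 37 ± 8.49 RPKM. Insertion sequence and phage genes had 36 up and 12 down of 249 (23 and 6 adjusted over the list alone; 40 and 31 with a replicate term; 147 and 8 after median-ratio rescaling). Their median log2 change was 0.31, or -0.06 with each library brought to a common sum of RPKM (camera adjusted p = 1.0e-04, and adjusted p = 0.69 with an estimated correlation).

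Between T270 and T540 146 genes rose and 116 fell of 6277 (limma). The sarcosine oxidase subunit genes META1_1545, META1_1546 and META1_1547 rose from 14 ± 5.66, 10.5 ± 4.95 and 10 ± 5.66 RPKM to 396 ± 91.9, 317 ± 95.5 and 272 ± 99.7. The oxidoreductase subunit genes META1_0602 and META1_0604 fell from 232 ± 19.8 and 389 ± 21.9 RPKM to 55.5 ± 20.5 and 95.5 ± 26.2. The dicarboxylate-type transporter gene dctP fell from 1257 ± 94 to 319 ± 119.5. Median-ratio rescaling gave 33 higher and 29 lower, and a replicate term 545 and 605. Leaving out replicate 1 of T540 left 2 calls and leaving out replicate 2 of T540 gave 551.

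**Figure D4:**
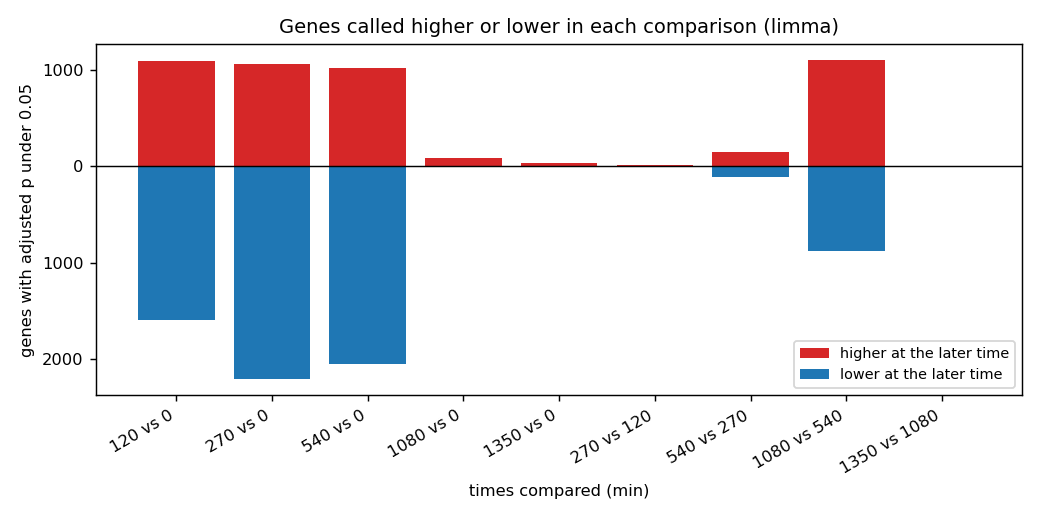
Bars give the number of genes with adjusted p under 0.05 (limma, 6277 genes) that were higher (up) or lower (down) at the later of the 2 times compared, in min. The 3 comparisons of T120, T270 and T540 with T0 and that of T1080 with T540 hold the most genes; T1350 against T1080 has 0.

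Between T540 and T1080 1100 genes rose and 883 fell of 6277 (limma). Of the ribosomal protein genes, rplI rose from 38.5 ± 26.2 to 1269.5 ± 759 RPKM, rpsF from 121 ± 60.8 to 3843 ± 2104 and rpsR from 109 ± 55.2 to 3032 ± 1185. META1_4500 fell from 1684 ± 531 to 44 ± 17 RPKM, the general stress gene META1_0650 from 2097 ± 1107 to 56 ± 21.2 and trhA from 2905 ± 1059 to 86.5 ± 16.3. The median log2 change over all genes was 0.28, and median-ratio rescaling gave 1285 higher and 1242 lower. With a replicate term 2313 were higher and 1299 lower, and without replicate 1 of T1080 1185 genes were called (511 higher), without replicate 2 of T540 1050 (452 higher).

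At T1080 83 genes differed from T0, 79 higher and 4 lower of 6277 (limma). Light-harvesting and mau genes led: pufA was at 15505 ± 14426 RPKM, pufB at 12376 ± 7484 and mauD at 4829.5 ± 763 against 110 ± 1.41. The reaction centre gene pufL was at 2249 ± 1954 against 37 ± 17 at T0, bchL, for protochlorophyllide reductase, at 1003 ± 773 against 19 ± 12.7, and bchY at 656 ± 359 against 15.5 ± 13.4. The named genes that were lower were META1_3271 at 44 ± 14.1 RPKM and the malate dehydrogenase gene mqo, which fell from 333 ± 272 to 25 ± 11.3. The median log2 change over all genes was -0.39, and median-ratio rescaling gave 90 higher and 26 lower. A replicate term gave 271 and 1416, and leaving out replicate 2 of T0 left 20 calls, replicate 2 of T1080 25. Of the genes lower than T0, leaving out 1 sample gave from 1 to 16.

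Photosynthesis and carotenoid genes were higher in 23 of 34 cases at T1080 (24 adjusted over the list alone; 24 up and 1 down with a replicate term; camera adjusted p = 1.5e-42, and adjusted p = 0.23 with an estimated correlation). The methanol oxidation and pyrroloquinoline quinone list was called higher with 2 of 14 genes up (2 adjusted over the list alone; 3 up and 3 down with a replicate term, 1 up after median-ratio rescaling; camera adjusted p = 2.7e-04, and adjusted p = 0.28 with an estimated correlation). Both genes are pqqA copies, META1_4628 at 82306 ± 40565 RPKM against 10677 ± 4193 and META1_4629 at 92571 ± 5546 against 12135 ± 1293. The ethylmalonyl-CoA list was called higher with 1 of 17 genes up, scpA at 511 ± 115 RPKM (4 adjusted over the list alone; 4 with a replicate term and 0 after median-ratio rescaling in limma; median log2 change 0.01, or -0.17 at a common sum of RPKM; camera adjusted p = 0.0017, and adjusted p = 0.69 with an estimated correlation). That call sets the ethylmalonyl-CoA list against all other genes and does not mean that the list rose from T0. The median over all genes was -0.39, and scpA belongs to the route from propionyl-CoA. Ribosomal protein genes were lower in 0 of 54 cases (0 adjusted over the list alone, limma), with a median log2 change of -0.53. Their camera call (adjusted p = 0.002) ended with a replicate term (0.21), after median-ratio rescaling (0.42) and with an estimated correlation (adjusted p = 0.73). Insertion sequence and phage genes were called higher (camera adjusted p = 8.6e-04, and adjusted p = 0.72 with an estimated correlation) although their median was -0.11 (0.21 after median-ratio rescaling) and mean -0.06; 5 rose of 249 and 0 fell (5 and 1 adjusted over the list alone; 7 and 18 with a replicate term).

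At T1350 33 genes were higher than at T0 and 1 lower of 6277 (limma), around a median log2 change of -0.12. The mau genes and amicyanin made up most of the largest, with mauJ at 946 ± 124 RPKM against 45 ± 1.41 and META1_2771 (MauE) at 2825 ± 1121 against 73.5 ± 3.54, beside the sarcosine oxidase gene META1_1548 at 176 ± 43.1 against 8 ± 4.24. The gene that was lower was META1_3271, at 38 ± 2.83 RPKM (log2 change -7.02, limma adjusted p = 5.5e-06). Ethylmalonyl-CoA genes were called higher as a list (camera adjusted p = 6.3e-04, and adjusted p = 0.69 with an estimated correlation) with 0 of 17 past the threshold over all genes in limma, 4 adjusted over the list alone and 1 with a replicate term. Their median log2 change was 0.03, or -0.18 at a common sum of RPKM. The call sets them against all other genes, with a median of -0.12 over all genes, and does not mean that the list rose from T0. Photosynthesis and carotenoid genes rose in 2 of 34 cases (25 adjusted over the list alone; 10 with a replicate term and 0 after median-ratio rescaling in limma; camera adjusted p = 9.0e-41, and adjusted p = 0.23 with an estimated correlation). Median-ratio rescaling gave 19 higher and 2 lower, and a replicate term 73 and 13. Without replicate 2 of T0, and likewise without replicate 2 of T1350, 18 genes were called.

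Between T1080 and T1350 limma called 0 of 6277 genes, with 58 at an unadjusted p under 0.05, and 0 with a replicate term (454 unadjusted), median-ratio rescaling (43) or quantile normalization (105). The gene pufA stood at 15505 ± 14426 and 5279 ± 6551 RPKM at these times, ccrA at 1026 ± 48.1 and 1295 ± 45.3, mauB at 5634 ± 1869 and 4929.5 ± 1817 and rpsF at 3843 ± 2104 and 4351 ± 192. The median log2 change over all genes was 0.27.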

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

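The tests between later times for these genes were chosen only after their opposite calls had been seen. The genes here are limited to those called higher than T0 at 1 later time and lower at another. There were 20 such genes. For each, the pair of such times with the largest difference was past the threshold in the direct test (limma, largest adjusted p = 0.0069), and 18 were higher at the earlier of the 2. Opposite calls make this difference larger than either change, at the same standard error. Passing the direct test was therefore largely set by the selection and adds no support. META1_2878 had opposite calls at T120 and T270 as well, with a direct test short of the threshold (limma adjusted p = 0.06) but past it with a replicate term (adjusted p = 0.005). After median-ratio rescaling 0 of the 20 kept both opposite calls in any pair of times (limma), while 15 stayed past the threshold in the direct test. All values are differences of the log2 change, later less earlier time.

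META1_2780, an exported protein of unknown function encoded beside the mau genes, differed most, by 4.76 between T120 and T1080: it was at 152 ± 35.4 RPKM at T0, 49.5 ± 13.4 at T120 and 1344 ± 18.4 at T1080. META1_5204, of the OmpA family, differed by -4.20 between the same times, and META2_1143, of unknown function, by 3.23 between T270 and T1080. The other 17 were higher than T0 at T120 and lower at T540. After median-ratio rescaling 0 of these 17 were called lower than T0 at T540 (limma; log2 changes from -0.78 to 0.0057). With it META1_2780 was no longer called at T120 (adjusted p = 0.1), META1_5204 at T1080 (0.3) or META2_1143 at T270 (0.41). Of the 17, META1_3372 (a short-chain dehydrogenase) differed by -2.76, META1_2906 (a glycosyl hydrolase) by -2.60, dgcA (META1_2870, an epimerase of Ala-Glu dipeptides) by -2.38, META1_4683 (a lactoylglutathione lyase) by -2.13, META1_3314 (a TetR regulator) by -1.92, META1_3345 (a glutathione S-transferase) by -1.88, META1_5078 (a phosphoglycerate mutase) by -1.68 and the thiolase META1_3455 of the ethylmalonyl-CoA list by -1.42. Neighbouring genes stood together. META1_0279, a CsbD-like stress protein, with META1_0280 and META1_0281 differed by -2.01, -2.06 and -2.05, and META1_2876, META1_2877 (an isomerase) and META1_2878 (a glycosyl transferase) by -2.15, -2.04 and -2.07. The rest were META1_1519 (a glycosyltransferase) at -2.08, META1_2717 at -1.90 and META1_4547 at -1.90. No explanation was tested for these genes.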

How the results depend on the processing

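The replicate term with rescaling or with an estimated correlation, the fits without rRNA and tRNA and the common sum of RPKM were chosen only after the data were seen. A pseudocount of 0.1 or 10 and no filter left every count within 1.5 times its value, as did leaving out rRNA and tRNA. No gene called in the fits reported was called with the opposite sign under median-ratio rescaling or quantile normalization. Under the replicate term no sign could turn, since each time has 1 sample of each replicate number and every log2 change stays as it was. The replicate term kept every gene called without it in those comparisons and changed no other gene call than by adding some; of 82 list calls it kept 76, with 6 others gained, and median-ratio rescaling 74.

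Where a count moved further, the cause was not tested. Genes changed over time went from 3158 to 5078 with the replicate term and 5148 with it and median-ratio rescaling. At T120 against T0 2683 became 4223 and 4367, and at T540 3065 became 4633 with both. At T1080 83 became 252 with quantile normalization, 1687 with the replicate term, 966 with both and 157 at a common sum of RPKM. At T1350 34 became 21 with median-ratio rescaling, 68 with only the 2 groups, 86 with the replicate term and 86 with both. Between T120 and T270 25 became 1 with median-ratio rescaling, 3 with quantile normalization, 0 without a variance trend, 0 with only the 2 groups (limma; 674 at an unadjusted p under 0.05 in the fit with all 6 times), 441 with the replicate term, 211 with both and 131 at a common sum. Between T270 and T540 262 became 399 with a filter of 50 RPKM, 62 with median-ratio rescaling, 65 without a variance trend, 54 with only the 2 groups, 1150 with the replicate term and 1278 with both. Between T540 and T1080 1983 became 990 with only the 2 groups, 3612 and 3941. Of 82 list calls 2 held with an estimated correlation and 0 with the replicate term as well.

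Leaving out 1 sample gave from 2582 to 3227 genes changed over time. Against T0 the range was 1821 to 2784 at T120, 2272 to 3391 at T270, 1915 to 3152 at T540, 20 to 105 at T1080 and 18 to 45 at T1350. Those that moved a total by over 1.5 times were replicate 2 of T540 (1915), replicate 2 of T0 and of T1080 (20 and 25 at T1080), and replicate 2 of T0 and of T1350 (18 each at T1350). Of the falls alone, 1595 at T120 became 980 without replicate 2 of T120, 1018 and 1039 without replicate 1 and 2 of T0, 2210 at T270 became 1408 without replicate 2 of T270, and 2048 at T540 became 1294 without replicate 1 of T0 and 1144 without replicate 2 of T540. Leaving out any sample moved the 4 falls at T1080, to between 1 and 16. Between T120 and T270 the range was 0 to 29: 3 without either sample of T0, 4 and 0 without replicate 1 and 2 of T120, 0 without either of T270 and 8 without either of T1350. Between T270 and T540 it was 2 to 551: 64 without either sample of T0, 136 and 116 without replicate 1 and 2 of T120, 13 and 12 of T270, and 2 and 551 of T540. Between T540 and T1080 it was 1050 (without replicate 2 of T540) to 2127, with 1185 without replicate 1 of T1080, and between T1080 and T1350 0 to 0 (limma, 58 at an unadjusted p under 0.05 with all samples). For the genes named by the rule, with 474 calls on all samples, leaving out any 1 sample moved the number of calls by no more than 1.5 times. A group left with 1 sample borrows its spread from the others, and the cause of these moves was not tested.

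Of 312 gene values, the replicate term brought 17 past the threshold and ended 0. Median-ratio rescaling ended 23, brought 4 past it and turned the sign of 1. Gene values in Results come from the fit without rescaling, and where no rescaled value stands beside them these 23 are not marked. The sign turned with a value past the threshold on 1 side for META1_5098 at T270 (-0.05; 0.66 with quantile normalization and 0.62 with the replicate term and rescaling) and for META1_3455 at T540 (-0.64; 0.0057 after median-ratio rescaling, with or without the replicate term); the cause was not tested. In 91 of the 7488 comparisons of a gene value with an alternative the sign turned with neither value past the threshold. Of 150 list medians 57 had a sign that differed between the scalings. Depth is unknown, and rounding to whole RPKM limits genes near the filter.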

Other observations

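The tests of the T540 samples, of rRNA and tRNA and of insertion sequences with each element counted once or by replicate were chosen only after the result was seen, as were the gene groups of the next 2 paragraphs; the other tests below were set out before their result.

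In a run of neighbouring genes, META1_1552, annotated as an FMN-dependent dehydrogenase, went from 22 ± 5.66 RPKM at T0 to 712 ± 7.78 at T270 and 1269 ± 119 at T540 (limma adjusted p = 5.6e-06 and 9.8e-06). META1_1548, a sarcosine oxidase subunit, went from 8 ± 4.24 to 16.5 ± 4.95 and 424 ± 89.1 (limma adjusted p = 0.11 and 3.2e-05). Beside the mau genes the regulator META1_2768 rose from 65 ± 0 to 839 ± 48.8 RPKM at T540, and the peroxidase gene tpx from 94 ± 17 to 444 ± 83.4. The genes napG (META1_2778) and napH (META1_2779), annotated MauM and MauN, are mau genes that the list's search pattern missed. They rose from 62.5 ± 12 and 36.5 ± 4.95 RPKM at T0 to 956 ± 75.7 and 478 ± 170 at T540.

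Of 5 genes annotated for sulfur oxidation, 3 were past the threshold at T1350 against T0. soxX rose from 38.5 ± 2.12 to 111 ± 14.1 RPKM, soxY from 87 ± 8.49 to 291 ± 90.5 and soxZ from 105 ± 7.78 to 388 ± 138 (limma adjusted p = 0.032, 0.032 and 0.023). soxA went from 43 ± 4.24 to 132 ± 48.8 RPKM and soxB from 30.5 ± 2.12 to 86 ± 21.2, past the threshold only with a replicate term (limma adjusted p = 0.0048 and 0.01, against 0.13 and 0.087). By replicon, the median log2 change at T540 was -0.77 over 5140 chromosomal genes and -0.14 over 1019 genes of the megaplasmid.

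Genes under 10 RPKM were fewer in replicate 1 (4.88 to 14.1% of genes) than in replicate 2 (15.8 to 29.9%), as weakly expressed genes were higher in replicate 1. Left-over rRNA and tRNA could, through its larger share of reads in replicate 1, only shift other genes down, by -0.0421 (log2, mean over the 6 times). Those with a mean under 20 RPKM were instead higher by a median of 0.87 (25th percentile 0.57). The sign of that shift was fixed by the larger share, so this was not an open test. A common cause of both excesses was not tested. Short transcripts kept in replicate 1 would give an excess that falls with coding length, but the Spearman correlation over the 1489 weakly expressed genes with a known length (87.5%) was 0.12. An even background of reads, as DNA might leave, stays open: over 1701 genes the excess had a median of 5.5 RPKM and an interquartile range 0.758 times as large, between the bounds set for and against it. A biological difference between the replicates was not tested, since the labels give none.

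Insertion sequence and phage genes were called higher against other genes at T120 to T540 by camera at the preset correlation, but not at the estimated correlation of 0.338 (adjusted p = 0.69 at each time). Weak expression alone is argued against: their median lay at percentile 100 of random lists matched on mean RPKM at each of the 3 times (0.60, 0.42 and 0.31 against medians of -0.49, -0.79 and -0.79; at a common sum of RPKM the list medians at T270 and T540 turn to -0.11 and -0.06). With 1 value for each of 71 elements or unnamed members the medians were -0.09, -0.10 and -0.16. Matched random lists then had medians of -0.50, -0.76 and -0.75 (percentiles 99.7 to 99.98). Over all 249 members, not counted by element, the excess over matched genes ran from 0.71 to 1.25 in the 2 replicates. Reads shared between copies could not be measured. The median change at T120 of members of elements with several copies (208) was 1.19 above that of members of single-copy elements (13). With each element counted once it was 0.65 above (30 against 13, permutation p = 0.043). A larger rise of the elements with several copies would give the same difference, so whether shared reads contribute stays open. A response of these genes to the change of substrate also stays open and was not tested.

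At T540 replicate 1 lay nearer to the late samples than replicate 2 did. Along principal component 1 a gap of that size already at T0 is argued against, as it was then 0.127 of that at T540 (6.42 against 50.5). This holds for that axis only. On component 2 replicates 1 and 2 lay at -29.0 and -0.33 at T0, and at -5.66 and 40.9 at T540. The SD over genes of the replicate difference was 0.53 log2 at T0 and 0.85 at T540, so the replicates differed at T0 as well. A lasting difference between the replicates stays open: replicate 2 lay higher at all 6 times, with gaps of 14.2, 29.4, 39.0 and 27.5 at T120, T270, T1080 and T1350, and the mean gap of the other 5 times was 0.462 of that at T540. That the culture of replicate 1 was further along may contribute: over genes, the replicate difference at T540 rose with the change from T270 to T1080 with a slope of 0.238, against -0.0022, 0.0091, 0.0951, 0.107 and 0.0087 at T0, T120, T270, T1080 and T1350. This is a hypothesis found and tested on the same samples, and these values do not separate it from a lasting difference.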
